A study of Mus musculus with 2 samples.

How the data were processed

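ChIP-seq libraries from E14 mouse ES cells were compared: 1 LUZP1 precipitation and 1 mock precipitation. Per the labels' design text, 300 µg of chromatin was used, and the DNA was sequenced on an Illumina Genome Analyzer II. Per the same text, the authors aligned reads to the mouse mm9 genome with Eland, allowing 1 mismatch, and called enriched regions with MACS. They then kept regions of 100 to 1000 bp, masked repeats and annotated the result with GPAT and Ensembl 57. Versions of these tools are not given in the sources used here, nor is whether the mock entered the peak calling. A GCN5 precipitation in the design text was not analysed here.

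The authors deposited mapped reads, 1 line each, as start and end positions with a read count of 1 in every line. All reads were 36 bp long. No position held more than 1 read with the same start and strand, and no plus and minus reads shared the same 36 bp, so repeated reads had been removed before deposit. This removes most amplification copies and limits how high a narrow peak can rise. The LUZP1 peak list deposited by the authors gives chromosome, start and end alone, with no score, fold or p-value and no gene name. It counts positions from 1: 33 of its 47 starts and 29 of its ends then fall on the 5′ end of a LUZP1 read, against 1 and 0 if it counted from 0. It holds 40 peaks of 104 to 262 bp followed by 7 of 304 bp or more, and 3 loci are listed more than once, so sums were taken over 44 loci. Chromosome lengths of the reference NCBIM37 (the assembly also called mm9) matched the reads, except for 1 mock read past a chromosome end. Genes came from the GENCODE annotation of that assembly (mouse release 1, Ensembl 65), which is later than the release named by the authors.

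Reads were extended to 200 bp from the 5′ end and counted where they overlapped a region. The mock to LUZP1 ratio of total reads, 0.649, scaled the libraries. A ratio carries the exact conditional binomial (Clopper-Pearson) 95% interval of its counts. With 1 library per group there was no test and no p-value, and these intervals measure counting error alone. They treat reads as independent and are too narrow to the extent that 2 reads are the ends of 1 fragment. An interval given with a median comes instead from the ranked values and covers the spread among peaks or promoters. Where the lower library had 0 reads the ratio was set against 3 reads, the upper limit that a count of 0 allows. Such a value leaves out counting error in the other library and is not a lower bound, so the interval's own lower bound is given with it. For the window scan, 500 bp windows needed 15 or more fragment midpoints and a scaled ratio of at least 5, with 1 added to both scaled counts, and the same scan was run with the libraries exchanged. Peaks were classed by the nearest feature in this order: an annotated snRNA gene within 500 bp, Malat1, a protein-coding start within 500 bp, any gene, or none.

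Gene lists were fixed before the data were examined: snRNA families of RNA polymerase II, non-coding RNAs of RNA polymerase III, small nucleolar RNAs with their own promoters, long non-coding RNAs, histones, pluripotency, housekeeping, ribosomal protein, silent in ES cells, ATAC and Mediator. For the RNA lists many symbols do not occur in the annotation. Of the symbols, 8 of 22, 5 of 16 and 4 of 11 matched for the first 3 lists and 6 of 8 for long non-coding RNAs, and all matched for the others. A matched family name takes in all annotated copies. A list's median was placed among 10000 random lists of the same size matched on summed reads. The genes named are those at every listed peak, those at the 10 LUZP1 windows and 5 mock windows outside the list with the highest lower bounds, and examples from the fixed lists. The scan gave fewer LUZP1 windows than that. The U2 copy named among the snRNA families, the reads around snRNA genes, the set of all coding starts and the tRNA-like sequences of the closing section were chosen after values had been seen.

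Fragment length was read from the distances between plus-strand and minus-strand 5′ ends, against the mean number of pairs 301 to 600 bp apart. To count such pairs once, a plus read and the first free minus read at a distance of 63 to 107 bp (LUZP1) or 47 to 186 bp (mock) were joined, which left 3467393 and 1909562 fragments. GC content was taken in 5116421 windows of 500 bp without unknown bases, and a ratio was divided by that of windows with the same GC content in steps of 2 percent. The share of sequences of 36 bases that occur once in the genome was counted for exact matches on both strands. A tRNA-like sequence had an A box and a B box 38 to 110 bp apart, flanked by arms of 7 bases of which at least 6 pair. No annotation of nuclear tRNA genes was at hand, so a locus classed as having no gene may hold a tRNA gene.

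The steps were tested on simulated data. The scan found 200 of 200 planted windows of 40 added midpoints and 0 others, but only 1 listed peak held that many LUZP1 reads, so this says little about finding peaks of the listed size. Of 200 coding starts raised 5-fold at the real depths, 100 had an interval above 1, and of 200 raised 2-fold, 14 had one, so most changes of that size at 1 promoter are beyond the reach of these libraries. Pooled over the 200, the ratios were 5.35 (4.78 to 6.00) and 1.98 (1.75 to 2.25). With 1000000 simulated fragments of 120 bp, the pair distance came out at 120 bp. Alternatives tried were unextended reads, 300 bp extension, peaks widened by 250 bp, other window sizes and thresholds, promoters of 1000 bp on each side, and scaling on 10000 bp bins. Extension to each library's own pair distance, pairs counted once, GC matching, ratios of reads summed over loci or over the promoters of a list, and sums without single loci, without Pgk1 or without tRNA-like sites near listed peaks were added after seeing the data. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Biopython 1.88, numba 0.67.0 and matplotlib 3.10.9.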

Results

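Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map LUZP1, a leucine zipper protein, on the genome of E14 cells. E14 is a feeder-independent mouse embryonic stem (ES) cell line of the 129P2/OlaHsd strain, used here at passages 25 to 30. The series concerns ATAC, a coactivator complex with histone acetyltransferase activity, and Mediator, the coactivator that connects transcription factors with RNA polymerase II, at non-coding RNA genes. The groups were a LUZP1 precipitation with rabbit serum (n = 1 library) and a mock precipitation (n = 1 library). The sample labels describe the mock as made with no antibody, whereas the design text describes it as made with GST. A GCN5 precipitation named in the design text was not analysed here.

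The LUZP1 library held 4214959 mapped reads of 36 bp, or 1.59 reads per kb of genome, and the mock library held 2734938, or 1.03 reads per kb. Mitochondrial DNA made up 0.0434% of LUZP1 reads and 0.174% of mock reads. The libraries differed in the spacing of their reads. Reads on opposite strands paired most often at 85 bp in LUZP1 and at 162 bp in the mock, at 14.0 and 17.7 times the background of chance pairs. They also differed in base composition: the LUZP1 to mock ratio rose from 0.542 in the tenth of 500 bp windows with the lowest GC content (95% counting interval 0.538 to 0.545) to 1.22 in the tenth with the highest (1.21 to 1.22). The X chromosome had a ratio of 0.863 (0.855 to 0.871). With 1 library per group no test between the conditions could be made, no difference below has a replicate check, and each interval of a ratio covers counting error only.

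**Figure D1:**
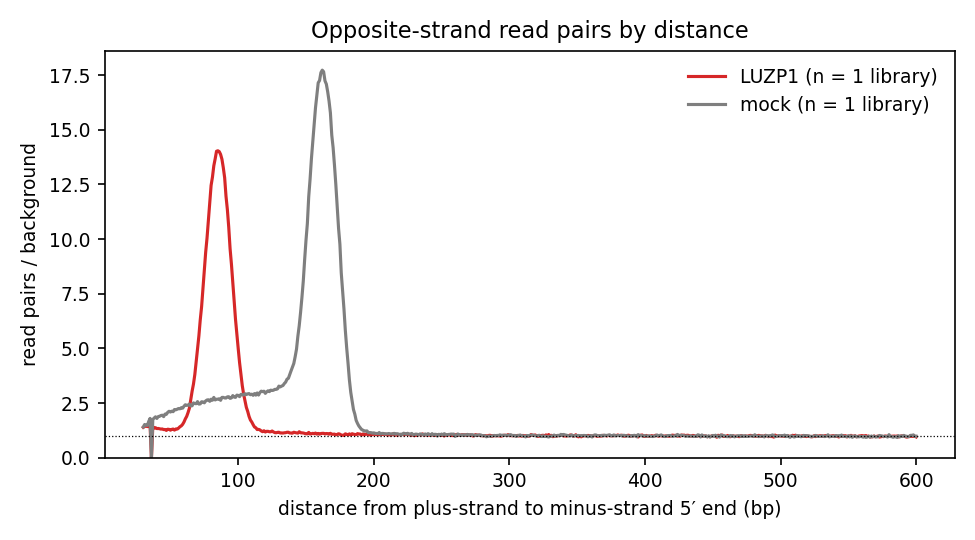
Number of read pairs on opposite strands (vertical axis, relative to the background of pairs 301 to 600 bp apart) against the distance between their 5′ ends in bp (horizontal axis), for the LUZP1 library (red) and the mock library (grey). The LUZP1 pairs peak at 85 bp and the mock pairs at 162 bp, and no pairs were found at 36 bp, the read length.

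The first question was where LUZP1 was enriched over the mock. The authors listed 47 LUZP1 peaks of 104 to 818 bp at 44 distinct loci, and these lay at small nuclear RNA (snRNA) genes, at the long non-coding RNA gene Malat1, at 8 protein-coding gene starts, inside other genes and between genes. Over the 44 loci the LUZP1 library had 543 reads and the mock had 72, a depth-scaled ratio of 4.89 (95% interval 3.82 to 6.35). The median ratio over the 47 peaks was 2.43, with an interval over the ranked peaks of 2.16 to 3.24. The 24 peaks that had 0 mock reads entered it set against 3 mock reads. In 22 of the 47 peaks the interval of the ratio lay above 1. With peaks widened by 250 bp the ratio over the loci was 2.92 (2.45 to 3.50), and with opposite-strand pairs at the fragment distance joined and counted once the median was 1.47. Of the 47 peaks, 27 then had 0 mock fragments and were set against 3, so that median is neither a plain ratio nor a lower bound.

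The signal was low in absolute terms. A listed peak held 6 to 50 LUZP1 reads, with a median of 10. The loci took 0.0129% of LUZP1 reads (exact Clopper-Pearson 95% interval 0.0118% to 0.0140%) and 0.00263% of mock reads (0.00206% to 0.00332%). The peaks were chosen on these reads, so the ratios are not independent evidence of enrichment. With such pairs counted once, the interval lay above 1 in 2 of the 47 peaks, on chromosomes 13 and 17 and both without an annotated gene, although the ratio over all loci was 4.32 (3.14 to 6.08).

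**Figure D2:**
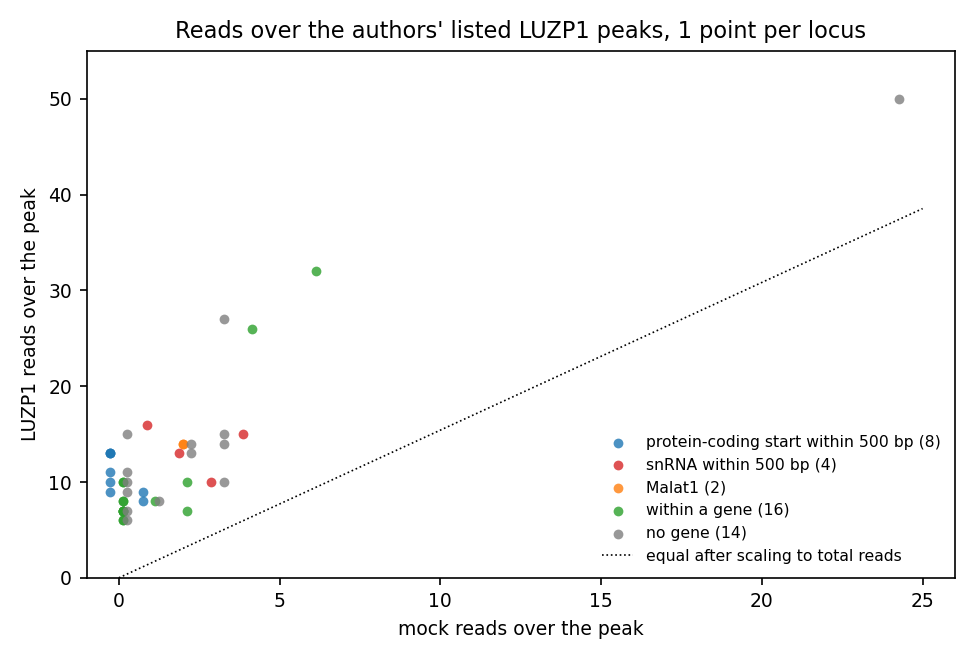
LUZP1 reads (vertical axis) against mock reads (horizontal axis) over the listed peaks, 1 point for each of the 44 loci, coloured by what the annotation holds there and shifted sideways by group so that points do not hide each other. All points lie above the dotted line of equal depth-scaled counts, and the point farthest right is the chromosome Y peak with 50 LUZP1 and 24 mock reads.

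Among the non-coding RNA genes, 4 loci with 6 listed peaks lay within 500 bp of an annotated snRNA gene. The spliceosomal snRNAs U1 and U2 act in the major spliceosome and U11 in the minor one. The loci together had 54 LUZP1 and 10 mock reads, a ratio of 3.50 (1.77 to 7.72). The U1 gene on chromosome 11 (87236369 to 87236532, plus strand of mm9, inside an intron of Tex14) had the highest ratio of them: its wide peak (87236290 to 87236891) held 16 LUZP1 reads and 1 mock read, a ratio of 10.4 (1.61 to 435). Its narrow peak (87236600 to 87236741) held 12 and 0, 2.60-fold when set against 3 mock reads, with a lower interval bound of 1.80. With pairs counted once the wide peak was at 5.51 (0.783 to 239) and the narrow one at 7 and 0, with a lower interval bound of 0.794. On such counts 0 of the 6 peaks had an interval above 1, and the loci together had 36 and 7, a ratio of 2.83 (1.24 to 7.54). The peak at the U1 gene of chromosome 3 (96132459 to 96132952) held 13 and 2 reads, a ratio of 4.22 (0.955 to 38.5). The peak at the U11 gene of chromosome 4 (131825690 to 131826167) held 10 and 3 reads, a ratio of 2.16 (0.557 to 12.2), and the wide peak at AC120136.3 on chromosome 1 (72301720 to 72302121) held 15 and 4, a ratio of 2.43 (0.775 to 10.1). For each of these last 3 genes alone enrichment over the mock was not detectable at this depth, whereas together they had 38 and 9 reads, a ratio of 2.74 (1.30 to 6.44). AC120136.3 (72301582 to 72301772) is annotated as an snRNA gene without a family, and its 191 bp were 99.0% identical to the closest annotated U2 copy.

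Read starts at these 4 snRNA genes numbered 44 in LUZP1 and 8 in the mock within 500 bp downstream, 8 and 6 within 500 bp upstream, and 6 and 0 within the genes. The downstream stretches hold listed peaks called on these reads, so the positions describe the listed loci and are not an independent comparison. The 6 LUZP1 read starts within genes were 4 at U11, which had 6 and 3 downstream, and 2 at U1 on chromosome 11. Reads can be placed unevenly here: 34.0% of the 36-base sequences of AC120136.3, 20.1% of those of U1 on chromosome 11 and 21.1% of those of U1 on chromosome 3 occur once in the genome, against 91.8% for U11. The downstream stretches reached between 92.6% and 100%, and the upstream stretches between 36.8% and 100%.

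Malat1, which gives rise to an abundant nuclear RNA, carried 2 listed peaks in its exon on chromosome 19 (5800079 to 5800896 and 5800961 to 5801470). Each held 14 LUZP1 and 2 mock reads, a ratio of 4.54 (1.04 to 41.2). With pairs counted once the ratios were 2.48 (0.513 to 23.6) and 4.41 (0.591 to 195), and together 3.12 (0.903 to 16.6), with all 3 intervals including 1. Within 500 bp of the Malat1 start, a stretch that neither peak reaches, enrichment was not detectable. There the LUZP1 library had 6 reads and the mock 5, a ratio of 0.779 (0.198 to 3.23).

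Protein-coding starts had the highest ratio of the peak groups. The 8 loci within 500 bp of one had 86 LUZP1 reads and 2 mock reads, a ratio of 27.9 (7.49 to 234), which rests on few mock reads: it was 50.6 without Kptn and 50.0 without 1700064H15Rik. The loci lay at Dedd, Dbndd2, Tmem101, Muted, 1700064H15Rik, Shprh, Zfp689 and Kptn. Dedd (chromosome 1, 173259299 to 173259430, exon), the Dbndd2 start (chromosome 2, 164286259 to 164286399, in exons of Sys1 and Gm14302) and Tmem101 (chromosome 11, 102017626 to 102017763, exon) each had 13 LUZP1 reads and 0 mock reads. Set against 3 mock reads each was at 2.81-fold, with a lower interval bound of 1.98. Muted had 11 and 0, Shprh 10 and 0, and Zfp689 9 and 0, with lower interval bounds of 1.63, 1.45 and 1.28. The peak beside 1700064H15Rik had 9 and 1 reads, a ratio of 5.84 (0.809 to 256), and that at Kptn 8 and 1, a ratio of 5.19 (0.696 to 230). With pairs counted once the loci together had 55 and 0, with a lower interval bound of 7.94, but 0 of the 8 had an interval above 1 alone; the lower bounds for Dedd, Dbndd2 and Tmem101 were 0.940, 0.940 and 0.794. In 1000 random placements of the 44 loci on their chromosomes, 0.489 loci on average, and at most 4, lay this close to a coding start. The placements were not matched on GC content, unique sequence or repeats, so they cannot tell binding from such features.

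Another 16 loci lay inside genes away from these classes, with 166 LUZP1 and 15 mock reads, a ratio of 7.18 (4.23 to 13.1). The intervals lay above 1 for Drg1 (32 and 6 reads, ratio 3.46, 1.43 to 10.1) and Sfi1 (26 and 4 reads, ratio 4.22, 1.46 to 16.6), both in introns on chromosome 11. These peaks span 244 and 154 bp, so the mock was itself above its mean of 1.03 reads per kb there. Copy number was not tested. Intervals also lay above 1 for Sh2b3 and 2210009G21Rik (10 and 0 each, lower bound 1.45) and for Tulp1 and Tpd52l2 (8 and 0 each, lower bound 1.11). The group had 102 and 9 with pairs counted once, a ratio of 6.24 (3.16 to 14.0), but 0 of the 16 had an interval above 1 alone. Drg1 was then at 2.48 (0.816 to 10.1) and Sfi1 at 3.58 (0.810 to 32.7), and Tulp1 and Tpd52l2, at 4 and 5 against 0, had lower interval bounds of 0.364 and 0.505. The other 10 loci, with intervals that reached 1, were in Mid1 with Gm15247, Dock2, Anks1b, Yeats2, Gm14005, Fam114a1, Micall1, Pif1, Stx17 and Acsf3 with Gm20388. Yeats2, which encodes an ATAC subunit, had 7 LUZP1 reads and 0 mock reads in an intron (chromosome 16, 20186857 to 20186973), with a lower interval bound of 0.935.

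The remaining 14 loci had no annotated gene and a ratio of 3.31 (2.36 to 4.74), or 6.07 (3.67 to 10.7) without the locus on chromosome Y. That locus was the peak with the most reads (2857823 to 2857999), with 50 LUZP1 and 24 mock reads and a ratio of 1.35 (0.815 to 2.30), not distinguishable from the mock at this depth. A peak on chromosome 17 (39981490 to 39981751) had 27 and 3 reads, a ratio of 5.84 (1.80 to 30.1). It had the highest GC content of the listed peaks, 69.8%, and its mock reads in 262 bp also exceeded the mean mock depth. Copy number was not tested there. A peak on chromosome 13 (23492662 to 23492795) had 15 and 0 reads, 3.24-fold when set against 3 mock reads, with a lower interval bound of 2.33. It lay 148 bp from a tRNA-like sequence, and the annotation used here does not cover nuclear tRNA genes. With pairs counted once the group was at 2.91 (1.87 to 4.72). The peaks on chromosomes 17 and 13 then kept an interval above 1. The former was at 4.68 (1.11 to 41.8), and the latter, at 12 and 0, had a lower interval bound of 1.53.

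A scan of 500 bp windows asked whether enrichment could be found without the authors' list. At 15 or more fragment midpoints and a scaled ratio of at least 5, 3 windows were higher in LUZP1, and 7 were higher in the mock. It met 1 of the 47 listed peaks, the one on chromosome 13. Only 8 of the listed peaks held 15 or more LUZP1 reads, so the threshold lay above the reads of most of them. Windows of 1000 bp gave 17 LUZP1 and 10 mock windows. At 10 or more midpoints and a ratio of 3 the counts were 139 LUZP1 and 41 mock windows, and the scan then met 16 listed peaks. The midpoint minimum applied to unscaled counts, and the LUZP1 library was the deeper 1. The numbers of LUZP1 and mock windows are therefore not like for like. The LUZP1 windows outside the list were an intergenic one on chromosome 3 (5860501 to 5861000, 18 and 0 midpoints, lower interval bound 2.85) and one on chromosome 16 (35981501 to 35982000, 31 and 2 midpoints, ratio 10.1, 2.56 to 86.7). The latter overlaps an exon of Gm15564 and lies within Kpna1.

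Among the mock windows, 4 overlapped exons of Atxn7, which encodes a subunit of the SAGA coactivator complex. The one with the most midpoints (chromosome 14, 14921501 to 14922000) held 61 mock and 0 LUZP1 midpoints, 31.3-fold when set against 3 LUZP1 midpoints, with a lower interval bound of 24.7. A window at the start of Pgk1, which encodes a glycolytic enzyme (chromosome X, 103382001 to 103382500), held 40 mock and 3 LUZP1 midpoints, a ratio of 20.5 (6.54 to 104). A window in Gm10222 (chromosome 1, 24619501 to 24620000) held 17 and 0, 8.73-fold when set against 3 LUZP1 midpoints, with a lower interval bound of 6.36.

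Since the title names non-coding RNA genes, the promoters of whole RNA families were compared, within 500 bp of each annotated start. Taken as families, they were not higher in LUZP1. The families of snRNAs made by RNA polymerase II (438 annotated copies of U1, U2, U4, U4atac, U5, U7, U11 and U12) had 1028 LUZP1 and 713 mock reads, a ratio of 0.936 (0.849 to 1.03). The interval lay above 1 for 1 copy, a U2 gene on chromosome 11 (101519552 to 101519742) with 9 and 0 reads, and below 1 for 10 copies. U11 (5 copies) had a ratio of 2.04 (0.841 to 5.65), U4 (43 copies) 1.29 (0.949 to 1.76) and U5 (10 copies) 0.573 (0.375 to 0.872). Non-coding RNAs of RNA polymerase III (1448 copies of U6, U6atac, 7SK, Y RNA and 5S rRNA) had a ratio of 1.002 (0.947 to 1.06), with 5 copies above 1 and 33 below. The 2 sides are uneven by depth alone: 4 mock reads against 0 put an interval below 1, whereas 8 LUZP1 reads against 0 were the fewest that put a copy above it. Over all 22367 protein-coding starts, 238 lay above 1 and 362 below. With pairs counted once 20 lay above 1, and those below were not counted. Small nucleolar RNAs with promoters of their own (53 copies) had a ratio of 0.942 (0.674 to 1.32). These sums do not separate transcribed from untranscribed copies.

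Within 500 bp of the start, promoters of the other lists gave intervals that included 1 in all but 1 case. Pluripotency genes had a pooled ratio of 1.17 (0.768 to 1.81), or 0.903 with pairs counted once. Their median, on counts with 1 added, was 1.75, with an interval over the ranked promoters of 0.491 to 2.77. It stood at percentile 97.2 of 10000 random lists matched on reads, although 0 of the 14 promoters had an interval above 1 and 2 had one below. The median was 1.03 with pairs counted once. Nanog had 9 LUZP1 reads and 1 mock read, a ratio of 5.84 (0.809 to 256), whereas Tcl1 had 2 and 9, a ratio of 0.144 (0.0152 to 0.697), and Zfp42 had 0 and 4. The ATAC list, in which Luzp1 itself was included, had 1.51 (0.927 to 2.51), with 7 and 1 reads at Luzp1. Mediator subunits had 0.795 (0.482 to 1.32), or 0.671 (0.460 to 0.980) with promoters of 1000 bp on each side, an interval below 1. The ratios were for histone genes 1.30 (0.751 to 2.31), ribosomal protein genes 1.02 (0.611 to 1.74), genes silent in ES cells 0.865 (0.474 to 1.60), and long non-coding RNA genes 0.767 (0.317 to 1.89). With pairs counted once histone genes were at 0.918 and ribosomal protein genes at 0.841, and with 1000 bp on each side genes silent in ES cells were at 1.06. The percentiles of the other lists ran from 12.9 for long non-coding RNA genes to 82.3 for histone genes. The exception was the housekeeping list, at 0.492 (0.333 to 0.721), which rested on Pgk1 with 7 LUZP1 and 43 mock reads. Without Pgk1 the ratio was 1.21 (0.715 to 2.11).

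**Figure D3:**
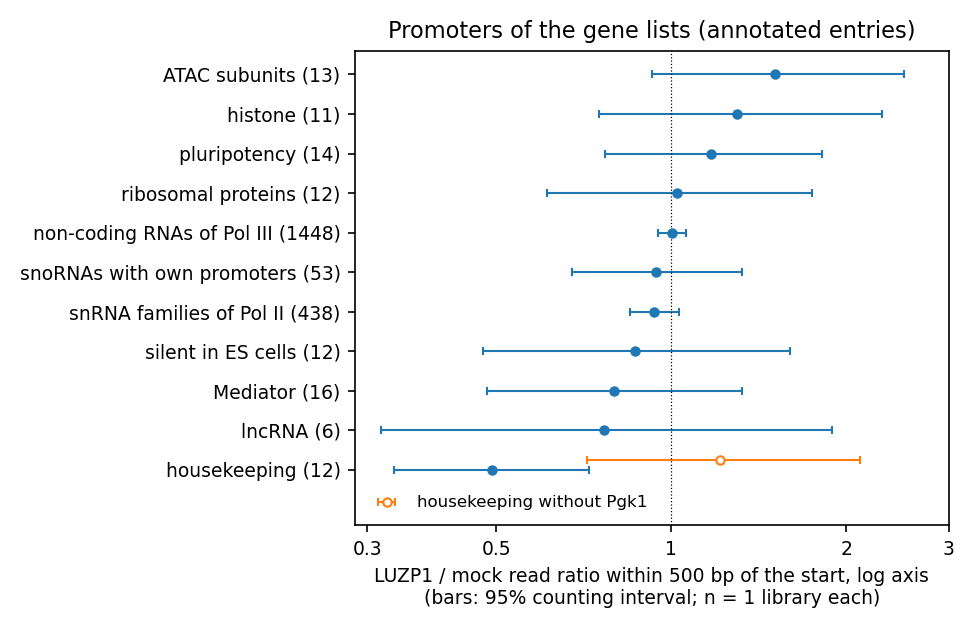
Depth-scaled LUZP1 to mock read ratio within 500 bp of annotated starts (horizontal log axis) for each gene list, with the number of annotated entries in parentheses; points are pooled ratios, bars are 95% counting intervals, and each group is 1 library. The housekeeping interval alone lies away from 1, at 0.333 to 0.721, and the open orange point shows the list without Pgk1, at 1.21.

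Over all 22367 protein-coding starts, the LUZP1 library had 65543 reads within 500 bp and the mock had 36256, a ratio of 1.17 (1.16 to 1.19). Against windows of the same GC content the ratio was 0.935 (0.923 to 0.947), so the direction depended on whether GC content was taken into account.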

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

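The tests of Atxn7 and of the read pairs were chosen only after the result was seen. The tRNA-like sequences and the set of all coding starts were also picked after the data had been examined, although the tests of GC content, fragment length and pair counting on them were written before their results were seen.

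LUZP1 reads exceeded mock reads over a set of sites that the comparisons do not use as such: 725 tRNA-like sequences had 2498 LUZP1 and 776 mock reads within 250 bp, a ratio of 2.09 (1.93 to 2.27), or 2.03 (1.87 to 2.21) without the 7 sites within 500 bp of a listed peak, and coding starts had the smaller ratio of 1.17. For the tRNA-like sequences the tables argue against GC content alone (1.90 against GC-matched windows, 1.75 to 2.06). They also argue against counting both fragment ends alone (1.87 with fragments counted once, 1.69 to 2.07). LUZP1 pairs over mock pairs of the same length gave 2.12 (1.46 to 3.21). At 85 bp, however, the mock library had 3656 pairs against a chance background of 1363 per bp. Many of its short pairs can thus be chance pairs, so this value cannot decide on shorter fragments. Short over modal mock fragments gave 1.29 (0.827 to 1.95), on 29 short pairs. That upper bound lay below the ratio of 2.09 but within its interval, so this test cannot decide. The explanations were tested 1 at a time and not together. For coding starts both tested explanations met their predictions, but neither is shown to be the cause. GC matching brought the ratio past 1, to 0.935 (0.923 to 0.947), an outcome that the prediction also allowed. Short mock fragments were themselves higher there than modal ones by 1.24 (1.16 to 1.32), although LUZP1 pairs over mock pairs of the same length still gave 1.08 (1.02 to 1.15). Both values rest on short mock pairs, many of which can be chance pairs. Binding of LUZP1 or of another target of the serum stays open and was not tested, as does recovery of open chromatin that differs between precipitations. The other RNA polymerase III families had a ratio of 1.002 (0.947 to 1.06). That ratio was counted within 500 bp and over all annotated copies, transcribed or not, so it is not like for like with the tRNA-like sites. Chance sites, found in the genome read backwards, were raised too, at 1.41 (1.11 to 1.81).

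Reads in the mock library that the comparisons of LUZP1 peaks do not use were concentrated in exons of Atxn7 on chromosome 14: 196 mock and 15 LUZP1 reads, a mock to LUZP1 ratio of 20.1 (11.9 to 36.7). Introns of the gene had 104 mock and 166 LUZP1 reads, a ratio of 0.966 (0.748 to 1.24), which argues against a higher copy number of the whole gene. DNA of a spliced Atxn7 copy in the mock library, such as a plasmid or an amplified product, may account for the exon reads, most of which lay in exon blocks 2 to 8 of 12. No biological explanation was tested.

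Pairs of reads on opposite strands exceeded chance in both libraries, by 34.3% of plus-strand reads in LUZP1 and 60.5% in the mock. More than 2000 bp from coding starts, tRNA-like sequences and listed loci the excess was 34.2% and 60.2%. That part kept 4014596 of 4214959 LUZP1 reads and 2618871 of 2734938 mock reads, so the excess could hardly change. It did not rest on the removed sites, but the comparison does not tell its causes apart. Sequencing of both ends of the same fragments would give such an excess, and is a candidate explanation. The counting intervals may then be too narrow. Pairing at binding sites other than those removed was not tested. No biological explanation was tested.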

How the results depend on the processing

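Fragments counted once, extension to the modal length, GC matching, pooled sums and values without Pgk1, the chromosome Y locus or tRNA-like sites near peaks were chosen after seeing the data. No paired analysis was possible because each group held 1 library. Of 145 values recomputed under an alternative, 122 stayed within the counting interval or within 1.5 times the count, 21 moved beyond it and 2 reversed. Among the 145 were 113 ratios, of which 12 fell on the other side of 1 from the main value: 2 whose main interval had excluded 1, and 10 list ratios or medians whose interval had included it. Keeping all reads moved nothing, since the files hold no repeats, so that setting tests nothing. Its values are counted in the 145 and in the 122, so these totals overstate the stability. The stricter peak list was not run because the list has no score.

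At the listed peaks the pooled ratio was 7.11 with unextended reads, 2.92 with peaks widened by 250 bp and 6.66 without the chromosome Y locus. The share of LUZP1 reads was 0.0112% unextended, 0.0168% widened and 0.00972% with fragments counted once. With fragments counted once 2 peaks had an interval above 1, since joined reads then give 1 count and not 2. The median was then 1.47, with 27 of the 47 peaks at 0 mock fragments and set against 3, so it is not a plain ratio. The scan depended on its settings, and its midpoint minimum was not scaled to depth, so LUZP1 and mock windows are not like for like. Windows of 1000 bp gave 17 LUZP1 windows, 10 mock windows and 2 listed peaks. At least 10 midpoints and a ratio of 3 gave 139 LUZP1 windows, 41 mock windows and 16 listed peaks. At least 25 midpoints and a ratio of 10 gave 0 LUZP1 windows, 3 mock windows and 0 listed peaks. The housekeeping ratio turned to 1.21 without Pgk1, and the Mediator interval fell below 1 with promoters of 1000 bp (0.671, 0.460 to 0.980). The ratio at tRNA-like sequences was 1.90 against GC-matched windows and 1.87 with fragments counted once. The ratio at coding starts turned to 0.935 against GC-matched windows, and was 1.08 with fragments counted once and 1.10 with the modal length. Except where given above, the cause was not tested. Depth limits single sites: of 200 simulated coding starts raised 2-fold at these depths, 14 had an interval above 1.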

Other observations

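The choice of tRNA-like sequences and all tests in this part came after the data had been seen. The LUZP1 to mock ratio around the 725 tRNA-like sequences was highest at the sequence itself, 2.39 (2.17 to 2.63) in the central 250 bp, and was 1.24 at 2000 bp upstream and 1.28 at 2000 bp downstream. The interval lay above 1 at 55 sites and below 1 at 8. The cluster on chromosome 13, near the histone genes, held 93 sites with a ratio of 3.21 (2.67 to 3.87) and 21 sites above 1. The other 632 sites had a ratio of 1.84 (1.68 to 2.02) and 34 sites above 1. The sites with the highest lower bounds lay near Gpx6 (chromosome 13, 21414682 to 21414754, 16 LUZP1 and 0 mock reads, lower bound 2.50), near Osbp (chromosome 19, 12085577 to 12085658) and near Dhx37 (chromosome 5, 125889842 to 125889912), the last pair with 15 and 0 reads each and a lower bound of 2.33. The same search in the genome read backwards, which keeps its base composition, gave 150 sites, with a ratio of 1.41 (1.11 to 1.81) and 0 sites above 1. With fragments counted once, 11 sites had an interval above 1. Unique 36-base sequences made up 71.8% of the tRNA-like sequences, 86.4% of their flanks and 86.5% of random windows.

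Of the 44 listed loci, 5 lay within 500 bp of a tRNA-like sequence, 4 of them with no annotated gene and the fifth beside 1700064H15Rik. In 1000 random placements the mean was 0.019 and the highest number was 1. These placements too were not matched on GC content, unique sequence or repeats.

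Besides Atxn7, 1 of the 9149 protein-coding genes with at least 10 exon reads in either library had a lower bound above 5 for the mock to LUZP1 ratio in exons: Utp18, with 16 mock and 0 LUZP1 exon reads and an intron ratio of 1.58 (0.991 to 2.52).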
